A study of Mus musculus with 150 samples.

How the data were processed

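Total RNA from tissues of wild-type inbred mice was hybridized, per the labels, as biotin-labelled target to 150 one-colour arrays of a single Affymetrix platform. The labels gave 100 arrays to 24 neural tissues of the strains 129, B6 and DBA, and 50 arrays to 10 body tissues of the strains 129, B6, DBA, AJ and C3H. A neural tissue had 4 to 7 arrays, and a body tissue had 1 array per strain. The strain written B6 or BL6 in the labels was read as a single strain. The unit of the deposited values is an intensity per probe set on a linear scale, with 5.99% of the values below 0. The software that made the intensities, its background correction and its scale factor are not given in the sources used here. The 75th percentile of the intensities ran from 165 to 184 over the 150 arrays, so the values had been brought to a common level before deposit. The number of arrays limits the precision of each mean.

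The 12488 probe sets included 66 controls, which were left out. Gene symbols came from the platform's annotation. Of the other 12422 probe sets, 10833 carried 1 symbol, 396 carried several and 1193 carried none. A gene was represented by the probe set with the highest mean, which left 8251 genes. That mean was taken over the 148 arrays used, where the plan had named all 150. The table that gave the order of genes along chromosomes was used only for which genes neighbour or contain each other, and no coordinates were printed.

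No further scaling was applied. Intensities below the 20th percentile of all values, 10.4, were raised to that floor, and values were then expressed as log2. A gene was tested in a fit if its strain-adjusted mean passed 5.73, the median of all log2 values, in at least 1 tissue of that fit. The column labelled 129 hippocampus replicate 1 and the column labelled DBA perirhinal cortex replicate 2 held identical values for all 12488 probe sets. Both were left out because the labels cannot both be right, and 148 arrays were used, 98 of them neural.

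Models were fitted with limma 3.58.1 in R 4.3.3, with a trend in the prior variance, and p-values were adjusted by the Benjamini-Hochberg method within a contrast. The threshold was an adjusted p of 0.05 and a log2 difference of 1. For strains it was an adjusted p of 0.05 and 1.5-fold, and for interactions the adjusted p alone. Neural against body tissue, and telencephalon against hindbrain and spinal cord, were tested on tissue means, since arrays of the same tissue only repeat that tissue. Whole hippocampus and whole cortex contain other dissected parts, so these tissue units are not fully independent. Every neural tissue was compared with the mean of the other 23, and every body tissue with the mean of the other 9, on arrays with strain as a term. Hippocampal subfields were compared on their 16 arrays, and the adipose depots within the fit of the 50 body arrays. The strains 129 and B6 were compared with tissue as a term in the 20 neural tissues that had both, and in the 10 body tissues within a fit of 5 strains. An F test covered the 5 strains, and interaction tests asked whether the strain difference varied among 19 neural tissues with at least 2 arrays of each strain, and between neural and body tissues. The placing of tissues in embryonic divisions followed textbook anatomy. Similarity of tissues within and between divisions was tested by permuting the division labels 100000 times, 1-sided.

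Gene lists for cell types, tissues, receptors and transcription factors were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over 56 pairs of list and contrast. Values are given at the preset correlation unless stated otherwise, and the estimated correlation gave a larger adjusted p in every pair. Before the data were examined, the lists, the comparisons, the thresholds, the alternatives and the rule for naming genes had been fixed. The rule named up to 4 called members of a list with the largest difference, the 5 genes with the largest difference in either direction, the 3 highest genes of every tissue, and the 8 largest strain differences in either direction. Genes named for the interaction with neural tissue fall outside it and were chosen after their values were seen. A gene at the floor on every array of a group is given with a lower bound for its fold.

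The fits were tested on simulated data of the same design, where 200 genes were changed by 1 to 3 on the log2 scale. Of these, 84.5% were recovered for the interaction with 1 neural tissue, at a change of 2, and 99.0% to 100% for the other comparisons. Smaller changes, near the thresholds, were not simulated. The changed genes had means well above the filter, and the noise was normal and independent, without a floor or shared pools. In the tests on tissue means, tissues varied less than in the data. The recovery therefore does not cover dim genes, shared animals or the full spread of tissues. The alternatives varied the floor, the scaling (quantile normalization, or the 75th percentile), the filter, the probe sets, the prior, the terms of the model and the units, and left out arrays or tissues in turn. The labels hold numbers that were read as pools of animals, and the pool, through statmod 1.5.0, entered as a replicate block in an alternative only.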

Results

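Expression was profiled in 24 neural and 10 body tissues of inbred mice. The neural arrays comprised 44 of strain 129, 47 of B6 and 9 of DBA, and every body tissue had 1 array of 129, B6, DBA, AJ and C3H. All retina arrays were B6, so the strain adjustment of retina rests on other tissues. Motor cortex had only B6 and DBA, and entorhinal and perirhinal cortex had only 129 and DBA. After removal of the pair of arrays with identical values, 148 arrays were compared. The median intensity of an array ran from 38.4 to 68.1, between 14.1% and 25.8% of its probe sets lay at or below the floor, and the ratio of Gapdh signal at the 3' and 5' ends ran from 0.748 to 1.41. Differences are given with their sign as log2 ± SE unless stated otherwise.

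The first question was which genes set the nervous system apart from other organs. Snap25, which encodes a membrane protein of the synaptic vesicle fusion machinery, was higher in neural tissue by 8.12 ± 0.39 (limma adjusted p = 2.20e-18, 24 against 10 tissues). Pcsk1n, an inhibitor of prohormone processing, was higher by 7.10 ± 0.47, and the glutamate receptor gene Gria2 by 6.88 ± 0.46. Gad1, which makes GABA, was higher by 6.66 ± 0.54, and Rtn1 by 6.41 ± 0.38. Among astrocyte genes, Aldoc was higher by 6.31 ± 0.31, Mt3 by 4.55 ± 0.28, and the water channel gene Aqp4 by 4.32 ± 0.46. The myelin genes Mobp and Mbp were higher by 6.02 ± 0.77 and 5.61 ± 0.65. In the other direction, the carbonic anhydrase gene Car3 differed by -5.97 ± 0.58 and Pck1, an enzyme of gluconeogenesis, by -5.13 ± 0.64. The fat cell genes Adipoq and Fabp4 differed by -4.60 ± 0.60 and -4.47 ± 0.48, and Plbd1 by -4.38 ± 0.28. Of 7195 genes tested, 1036 were higher and 1005 lower in neural tissue.

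Neuronal genes were higher as a class. Of 20 neuronal genes tested, 19 were higher, and 19 also passed adjusted over the list alone (camera adjusted p = 1.12e-16, but 0.0189 with an estimated correlation). Of 11 astrocyte genes 10 were higher, 10 adjusted over the list alone (1.59e-07, but 0.0207 with an estimated correlation). Of 10 myelin genes 8 were higher, while Gsn was lower by -1.81 ± 0.56, which made 9 adjusted over the list alone (0.00208). The myelin call was lost with an estimated correlation, at adjusted p = 0.256 with an estimated correlation. Genes of dividing cells went the other way: 13 of 16 were lower in neural tissue, 13 adjusted over the list alone (0.000311), among them Cdk1 by -2.28 ± 0.44 and Birc5 by -1.98 ± 0.43, but adjusted p = 0.331 with an estimated correlation. The mean log2 level of the list was 8.65 in thymus, 7.99 in spleen and 7.52 in testes, while the other 7 body tissues stood at 4.74 to 5.37 and neural tissues at 4.54 to 5.30. None of 10 microglial genes passed, 0 adjusted over the list alone (0.497), with 4337 genes in the whole comparison at an unadjusted limma p under 0.05. Of 10 endothelial genes, Slc2a1 was higher by 3.08 ± 0.28 with 1 other gene and Cdh5 lower by -2.24 ± 0.34 with 3 others, 6 adjusted over the list alone (0.270). The 3 red blood cell genes were lower, 3 adjusted over the list alone (0.0662). Hba-a1 had the smallest difference of them and lost its call under quantile normalization, at -0.72, and with any of 17 of the 34 tissues left out in turn, down to -0.81 without heart.

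Each neural tissue was then compared with the rest, to find the genes that mark it. Retina carried Gnat1, the rod transducin, at 9.95 ± 0.09 above the other tissues (limma adjusted p = 7.62e-86, 4 arrays), and Sag and Tulp1 at 8.79 ± 0.21 and 8.33 ± 0.27. In pituitary the hormone genes Prl, Cga and Pomc were higher by 9.37 ± 0.41, 8.34 ± 0.28 and 8.21 ± 0.26. Choroid plexus, which secretes cerebrospinal fluid, had Folr1, Ttr and Kl higher by 7.82 ± 0.40, 7.61 ± 0.72 and 7.46 ± 0.40. Ttr was the brightest probe set on all 4 choroid plexus arrays, and if its signal was saturated there, the size of its difference is too small. Hypothalamus had the peptide genes Avp, Oxt and Hcrt higher by 7.80 ± 0.21, 4.61 ± 0.16 and 4.49 ± 0.24. The bed nucleus of the stria terminalis had the same trio, at 4.85 ± 0.21, 4.00 ± 0.16 and 3.88 ± 0.24. Its nearest tissue in profile was hypothalamus (r = 0.670), and whether its dissection held hypothalamic tissue was not tested. The trio is therefore not shown to mark the bed nucleus itself. Cerebellum had the GABA receptor subunit Gabra6 higher by 7.07 ± 0.30 and Car8 by 6.03 ± 0.28. Olfactory bulbs had Dlx1, S100a5 and Omp higher by 5.64 ± 0.12, 5.60 ± 0.25 and 5.01 ± 0.28. Striatum had Rxrg higher by 4.95 ± 0.19, and the dopamine receptor gene Drd2 by 3.63 ± 0.15.

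Along the brainstem the markers overlapped. Klk6, a protease gene of myelinating cells, was higher in spinal cord, pons and medulla by 5.08 ± 0.23, 4.45 ± 0.23 and 4.17 ± 0.23. Vamp1 was higher in the same tissues by 4.02 ± 0.30, 3.91 ± 0.30 and 4.01 ± 0.30. En1, a transcription factor of the midbrain and hindbrain border, was higher in inferior colliculi by 4.32 ± 0.20 and in periaqueductal grey by 3.49 ± 0.20. Shox2 was higher in inferior colliculi, superior colliculi and midbrain with thalamus by 4.30 ± 0.21, 3.75 ± 0.21 and 3.50 ± 0.21. The dopamine transporter gene Slc6a3 was higher in midbrain with thalamus by 3.60 ± 0.34, and Ddc in periaqueductal grey by 3.58 ± 0.21. In forebrain, Tbr1 was higher in cortex by 4.16 ± 0.18, in motor cortex by 4.08 ± 0.19 and in amygdala by 3.38 ± 0.18. Hoxb5 was higher in medulla by 4.79 ± 0.20 and Hoxa7 in spinal cord by 3.89 ± 0.09.

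Over the 24 tissues and 6361 genes, 3013 genes were higher in at least 1 tissue and 2373 lower. Choroid plexus had 984 higher and 1203 lower, pituitary 907 and 808, and retina 826 and 789. Among brain and cord tissues, the counts were 281 and 136 in spinal cord, 244 and 131 in olfactory bulbs, 241 and 261 in cerebellum, and 204 and 145 in striatum, and fell to 82 and 89 in inferior colliculi. Over those 21 tissues alone, 1307 genes were higher and 1063 lower in the same fit. Quantile normalization shifted the median of all genes in retina by -0.11.

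**Figure D1:**
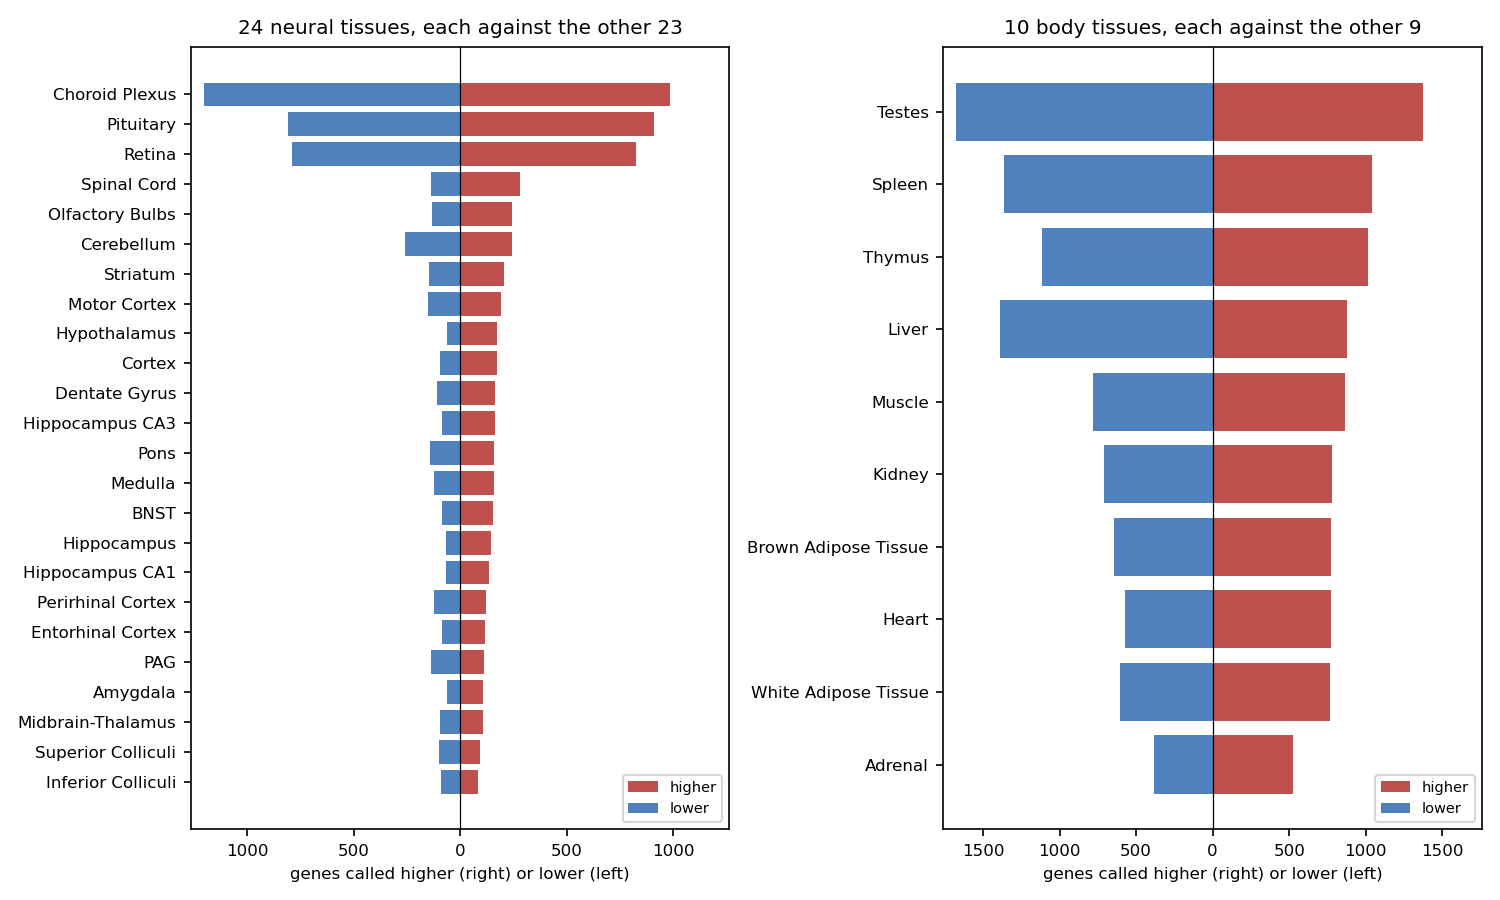
Number of genes higher and lower in every tissue than in the mean of the other tissues of its kind (horizontal axis, genes past the threshold), with neural and body tissues apart. Choroid plexus, pituitary and retina exceeded every brain and cord tissue, and testes had 1376 genes higher and 1676 lower.

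The listed markers of a tissue were high where they were listed. All 15 retinal genes were higher in retina, 15 adjusted over the list alone (camera adjusted p = 3.49e-21), all 10 pituitary genes in pituitary, 10 adjusted over the list alone (7.19e-11), and all 6 striatal genes in striatum, 6 adjusted over the list alone (6.07e-18). The figures were 11 of 12 in cerebellum, 11 adjusted over the list alone (2.44e-22), 9 of 12 hypothalamic genes, 9 adjusted over the list alone (1.31e-21), and 8 of 9 in olfactory bulbs, 8 adjusted over the list alone (3.50e-27). In choroid plexus all 7 were higher, 7 adjusted over the list alone (7.20e-06), but adjusted p = 0.0511 with an estimated correlation. There, 3 of 10 endothelial genes were higher, led by Eng at 2.23 ± 0.12, and Cldn5 was lower by -1.71 ± 0.14, 4 adjusted over the list alone (0.303). In spinal cord 9 of 10 myelin genes were higher, led by Ugt8a at 3.11 ± 0.23, 9 adjusted over the list alone (1.28e-14). Hox genes, which set position along the body axis, were higher for 12 of 18 in spinal cord, 12 adjusted over the list alone (3.68e-14), and for 6 of 18 in medulla, 6 adjusted over the list alone (1.70e-05). The list held 39 Hox genes, of which 31 were on the arrays and 18 passed the filter. A gene can pass it through spinal cord or medulla alone, so the shares among tested genes favour those tissues.

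A further question was whether adult regions still carry the pattern of the embryonic vesicles they come from. Nrgn, a postsynaptic calmodulin-binding protein gene, was higher in the 12 telencephalic tissues than in pons, medulla, cerebellum and spinal cord by 5.77 ± 0.60 (limma adjusted p = 1.38e-05). Tbr1, a transcription factor of cortical projection neurons, was higher by 5.31 ± 0.56, Kalrn by 5.25 ± 0.61, the telencephalic adhesion gene Icam5 by 4.69 ± 0.36 and Ptk2b by 4.46 ± 0.36. Dlx1 lay at the floor on all 16 hindbrain and cord arrays and was at least 9.07-fold higher in telencephalon, a call that was lost with the floor at the 40th percentile. Higher in hindbrain and cord were Klk6 (-4.80 ± 0.55), Vamp1 (-4.17 ± 0.65), Syt2 (-3.86 ± 0.57), Sh3bgr (-3.08 ± 0.28) and Hoxb5 (-2.97 ± 0.47). The astrocyte calcium-binding gene S100b was also higher there (-1.72 ± 0.13). In all, 206 genes were higher and 190 lower in telencephalon.

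Regional transcription factors differed along the same axis. Forebrain transcription factors were higher in telencephalon for 5 of 7 genes, 5 adjusted over the list alone (camera adjusted p = 0.000193). Of 8 midbrain and hindbrain factors 4 were lower, 4 adjusted over the list alone (0.000642), with Irx3 at -1.95 ± 0.18. Of 11 glutamate receptor genes 4 were higher, with Grin2b at 1.66 ± 0.19, and 1 lower, 5 adjusted over the list alone (0.00927). Of 10 immediate early genes 3 were higher, Nr4a1 (2.48 ± 0.51), Egr1 (2.44 ± 0.41) and Junb (1.87 ± 0.26), 4 adjusted over the list alone (0.00180). Of 10 myelin genes 8 were lower, with Ugt8a at -2.62 ± 0.56, 8 adjusted over the list alone (0.000164). Of 11 astrocyte genes 2 were lower, 3 adjusted over the list alone (0.0205), of 18 Hox genes 3, 3 adjusted over the list alone (5.72e-05), and of 4 glycinergic genes 2, with Slc6a9 at -1.80 ± 0.27, 2 adjusted over the list alone (0.00189). These calls were lost for glutamate receptors (adjusted p = 0.0645 with an estimated correlation), immediate early genes (adjusted p = 0.182 with an estimated correlation), myelin (adjusted p = 0.217 with an estimated correlation), astrocytes (adjusted p = 0.221 with an estimated correlation), Hox genes (adjusted p = 0.217 with an estimated correlation) and glycinergic genes (adjusted p = 0.0528 with an estimated correlation). Neuronal genes split evenly, 2 higher and 2 lower of 20, 4 adjusted over the list alone (0.328), with Stx1a at 3.04 ± 0.53 and Nefm at -2.55 ± 0.51. Monoaminergic and cholinergic genes had 1 higher and 2 lower of 9, 3 adjusted over the list alone (0.173), and GABA-A receptor genes 2 higher of 8, 3 adjusted over the list alone (0.259). Some calls of listed genes ended with single tissues left out. Hoxa5 (-1.92) and Hoxb6 (-1.32) were lost without medulla (limma adjusted p = 0.0990 and 0.0962) and without spinal cord (0.0872 and 0.114), which left Hoxb5 of the 3 Hox genes. Glra1 (-1.05) stood at -0.97 without medulla and -0.87 without spinal cord, which left Slc6a9 of the 2 glycinergic genes. Without spinal cord, limma also lost Mal and Mobp of the myelin genes (adjusted p = 0.105 and 0.0842) and Neurod6 of the forebrain factors (0.0809). Nr4a2 of the monoaminergic genes and Cplx1 of the neuronal genes were lost there too (limma adjusted p = 0.110 and 0.109). Each of these genes was also lost without medulla and without pons. Neurod6 was lost without cerebellum as well (limma adjusted p = 0.0506), and Cplx1 without CA1, at -0.96. Ddc was lost without pons and without medulla (limma adjusted p = 0.164 and 0.102). Gata3 was lost without pons, at -0.60, and En2 stood at -0.62 without cerebellum.

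On average, tissues of the same division had closer profiles. The mean correlation across genes of gene-centred tissue profiles was 0.226 over 82 pairs within a division and -0.224 over 128 pairs between divisions, a difference of 0.449 (permutation p = 1e-05, the smallest the resamples can give). Pons and medulla, at 0.882, and dentate gyrus and CA3, at 0.864, were close pairs. For 19 of 21 tissues the nearest tissue was of the same division. The bed nucleus of the stria terminalis and the hypothalamus, at 0.670, were each other's nearest tissue across the boundary. Hindbrain and cord lay nearer to diencephalon and midbrain, at a mean of 0.213, than to telencephalon, at -0.333. Within divisions the mean was 0.474 in hindbrain and cord, 0.365 in diencephalon and midbrain, and 0.182 in telencephalon, which is below the 0.213 between the other pair of divisions. Each gene was centred on the unweighted mean of the 21 tissues, 12 of them telencephalic. That weighting shifts the correlations, so the ranking of the division means does not by itself show which divisions are closer. Genes are not independent replicates, and whole hippocampus and whole cortex contain other dissected parts.

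**Figure D2:**
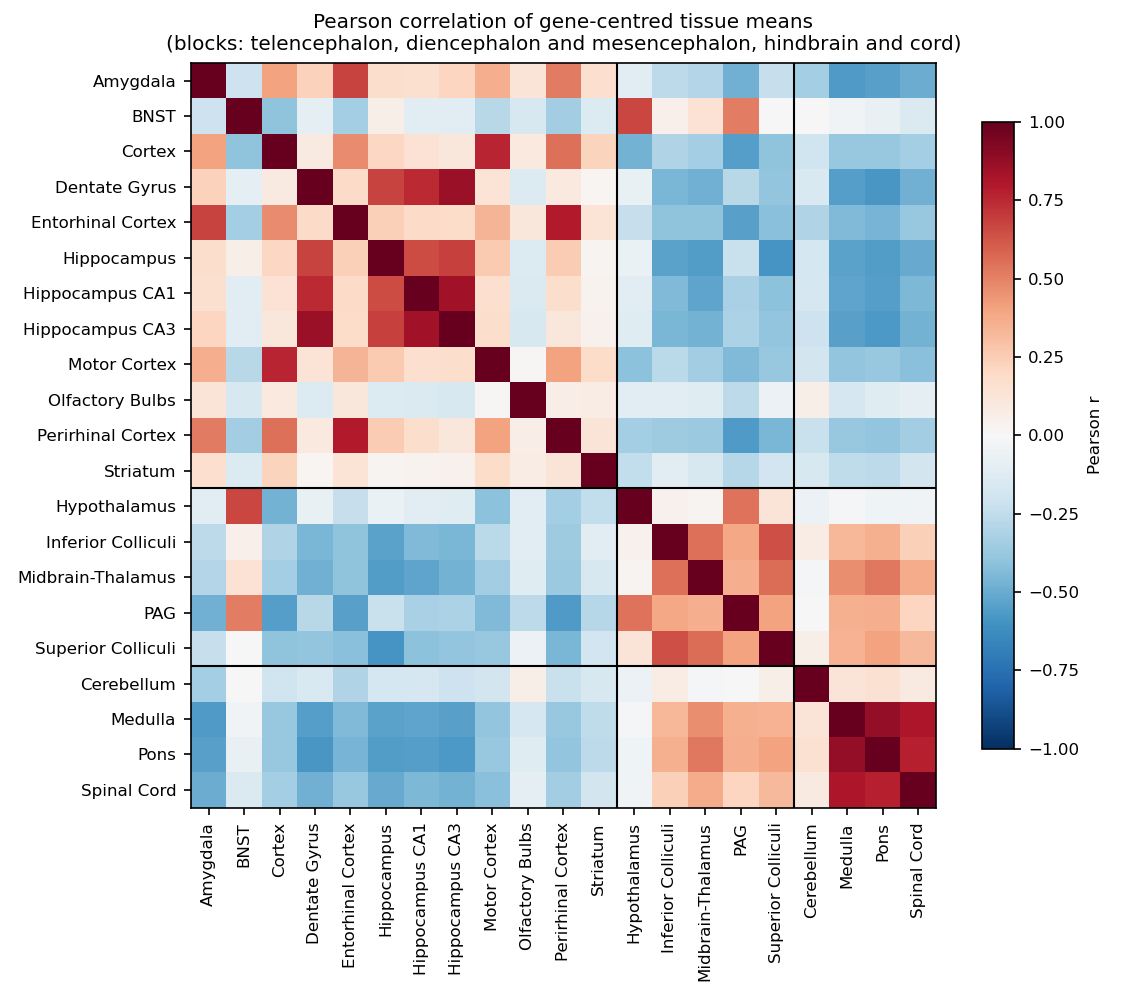
Pearson correlation across genes between the gene-centred mean log2 profiles of the 21 brain and cord tissues, ordered by embryonic division on both axes. The mean was 0.226 within divisions and -0.224 between them.

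Within the hippocampus the subfields were compared with one another. Pbx3, a homeobox cofactor gene, was higher in CA1 than in dentate gyrus by 2.15 ± 0.37 (limma adjusted p = 0.00773, 7 against 4 arrays), Stac by 2.03 ± 0.38, Ccn3 by 1.87 ± 0.31, Klf5 by 1.84 ± 0.38 and Ldb2 by 1.84 ± 0.30. The CA1 marker Wfs1 was higher by 1.71 ± 0.33. Lower in CA1 were Frzb by -2.71 ± 0.59, the calcium-binding gene Calb2 by -2.13 ± 0.28, Npy2r by -1.77 ± 0.41, Dsp by -1.75 ± 0.36 and Mycl by -1.60 ± 0.32. Of 4989 genes, 23 were higher and 16 lower in CA1. It fell to 20 with the Gapdh 3' to 5' ratio as covariate, which ran from 0.969 to 1.41 on CA1 arrays and from 0.974 to 1.06 on dentate gyrus arrays, and was 63 with all neural arrays in the fit. The count ran from 15 without dentate gyrus B6 replicate 1 to 60 without CA3 DBA replicate 1. Without any filter on dim genes 7 genes passed the threshold, Calb2 among them, and Klf5, Wfs1, Frzb, Npy2r, Dsp and Mycl each lost the call with some single array left out, as Npy2r did without dentate gyrus B6 replicate 2 (adjusted p = 0.120). limma called 0 genes between CA1 and CA3 (282 at an unadjusted p under 0.05), but 11 without CA3 DBA replicate 1, and 0 between CA3 and dentate gyrus (223 at an unadjusted p under 0.05). With all neural arrays in the fit these counts were 7 and 9.

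The CA1 and dentate gyrus lists shifted in the direction of their names, and the CA3 list did so only against CA1. The 3 CA1 genes were higher in CA1 than in dentate gyrus, 3 adjusted over the list alone (camera adjusted p = 2.77e-07). Without CA1 129 replicate 1 only Man1a of the 3 was called by limma, with Wfs1 at an adjusted p of 0.0537 and Pou3f1 at 0.0548, and Pou3f1 lost the call with any of 11 arrays left out. Against CA3 none of them passed, 0 adjusted over the list alone (0.00233), and adjusted p = 0.0692 with an estimated correlation. Of 5 dentate genes 2 were lower in CA1, 2 adjusted over the list alone (3.05e-05), and none lower in CA3, 1 adjusted over the list alone (1.38e-07). Neither of the pair, Dsp (-1.75) and Npnt (-1.30), was called against CA1 by limma without dentate gyrus 129 replicate 1 (adjusted p = 0.0869 and 0.0702) or B6 replicate 1 (0.0999 and 0.0890). None of 4 CA3 genes was called against CA1, 1 adjusted over the list alone (1.01e-05, lower in CA1), or against dentate gyrus, 0 adjusted over the list alone (0.0202, lower in CA3), where adjusted p = 0.241 with an estimated correlation. There Nptx1, Bok and Homer3 were lower in CA3, by -0.73, -0.50 and -0.47, against the list's name. Of 9 immediate early genes Nr4a1 and Egr1 were higher in CA1 than in dentate gyrus by 1.73 ± 0.36 and 1.15 ± 0.26, 3 adjusted over the list alone (0.0119), but adjusted p = 0.221 with an estimated correlation, and both lost the call with single arrays left out, Egr1 at 1.00 without CA1 129 replicate 2 and Nr4a1 at an adjusted p of 0.0850 without dentate gyrus 129 replicate 2.

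The body tissues were compared in the same way. Testes had Tnp2 and Prm1, which pack sperm chromatin, higher by 9.73 ± 0.42 and 9.32 ± 0.64 (limma adjusted p = 5.18e-24 and 4.95e-17, 5 arrays). In liver Apoa1, a lipoprotein gene, was higher by 9.51 ± 0.54, Mug-ps1 by 9.42 ± 0.29 and Cyp2d10 by 9.41 ± 0.20. Heart had Myh6, Tnni3 and Myl2 higher by 9.32 ± 0.33, 9.20 ± 0.27 and 8.74 ± 0.59, and skeletal muscle Tnnt3, Tnni2 and Atp2a1 by 8.24 ± 0.54, 8.22 ± 0.41 and 7.99 ± 0.63. Kidney had Miox, Dnase1 and Kap higher by 9.18 ± 0.35, 8.41 ± 0.29 and 8.25 ± 0.77. Adrenal had Cyp11a1, an enzyme of steroid synthesis, higher by 7.62 ± 0.19, with the secretory granule genes Chgb and Scg2 at 7.55 ± 0.21 and 7.23 ± 0.13. Thymus had Myb, Cd8b1 and Cd8a higher by 7.11 ± 0.32, 7.08 ± 0.35 and 6.94 ± 0.30, and spleen the immunoglobulin genes Igkv6-14, Igkv1-133 and Igkv6-23 by 6.85 ± 0.35, 6.75 ± 0.33 and 6.68 ± 0.55. Of 6680 genes, 4955 were higher in at least 1 tissue and 4175 lower. Testes had 1376 higher and 1676 lower, spleen 1038 and 1362, thymus 1013 and 1118, liver 876 and 1387, and adrenal 527 and 385.

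Body tissue lists followed their tissues. All 13 liver genes (camera adjusted p = 3.68e-14), all 13 heart genes (6.65e-19), all 13 testis genes (1.01e-10), all 11 adrenal genes (2.44e-22), all 10 kidney genes (2.86e-13), all 10 B cell genes in spleen (1.39e-09) and all 8 fat cell genes in white fat (1.04e-10) were higher, with the same counts of 13, 13, 13, 11, 10, 10 and 8 adjusted over the list alone. The counts were 12 of 13 for skeletal muscle, 12 adjusted over the list alone (3.92e-10), 9 of 10 for thymocytes, 9 adjusted over the list alone (9.36e-10), and 7 of 8 for brown fat, 7 adjusted over the list alone (9.81e-08). With an estimated correlation the camera adjusted p was 0.0489 for skeletal muscle, 0.00505 for liver and 0.00724 for testis, and lowest for adrenal, at 3.36e-10. Genes of dividing cells were higher in thymus for 16 of 16, 16 adjusted over the list alone (1.11e-09), led by Top2a at 4.89 ± 0.31 and Rrm2 at 4.28 ± 0.32, with adjusted p = 0.0680 with an estimated correlation.

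The pair of fat depots was compared directly. Cox7a1, a respiratory chain subunit gene, was higher in brown than in white fat by 7.41 ± 0.35 (limma adjusted p = 6.23e-21, 5 against 5 arrays), and Ucp1, which uncouples respiration to make heat, by 7.04 ± 0.40. Fabp3, Cidea and Kng1 were higher by 6.94 ± 0.36, 6.94 ± 0.66 and 5.65 ± 0.35. Lower in brown fat were the leukocyte antigen gene Cd52 (-6.42 ± 0.64), Plac8 (-4.96 ± 0.52), Ptgs2 (-4.78 ± 0.53) and Penk (-4.36 ± 0.32). Ly6f lay at the floor on all 5 brown fat arrays and was at least 18.4-fold lower. In total 836 genes were higher and 814 lower. All 8 brown fat genes were higher, 8 adjusted over the list alone (camera adjusted p = 3.05e-10), and 3 of 8 general fat cell genes were lower, 3 adjusted over the list alone (0.0907), with Nnat at -3.87 ± 0.38, Retn at -2.86 ± 0.40 and the leptin gene Lep at -2.49 ± 0.31. Of 8 lymphocyte genes Ighm and Cd74 were lower by -2.50 ± 0.45 and -2.04 ± 0.33, 2 adjusted over the list alone (0.463), where the median of the list was 0.08, its mean -0.42 and the direction of the test down. Skeletal muscle genes differed as well: 12 of 13 were higher in brown fat, and 235 of the 836 genes higher there were also higher in skeletal muscle than in the other body tissues, which leaves 601.

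Strain differences in the nervous system were tested between 129 and B6. Pam, an enzyme that amidates peptide hormones, was higher in 129 by 3.46 ± 0.13 (limma adjusted p = 1.10e-34, 39 against 41 arrays), in 20 of 20 tissues. The actin regulator Cap1 was higher by 2.53 ± 0.08, Gdpd3 by 2.49 ± 0.11, Serpina3n by 2.31 ± 0.09, Ocel1 by 1.65 ± 0.07, the retrovirus restriction gene Fv1 by 1.56 ± 0.09, Hbb-b2 by 1.55 ± 0.11 and Gnb1 by 1.43 ± 0.05. Lower in 129, in all 20 tissues, were the noncoding host genes Snhg6 (-3.04 ± 0.07) and Gas5 (-2.82 ± 0.05), Arcn1 (-2.57 ± 0.11), Pttg1 (-2.37 ± 0.09), a probe set annotated to Mir686 (-2.29 ± 0.04), Pla2g12a (-2.15 ± 0.07), AI506816 (-2.04 ± 0.10) and Fgfr1op2 (-1.84 ± 0.07). In a fit of all probe sets without the filter, the other probe sets of Snhg6, Pttg1, Pla2g12a and AI506816 did not pass the threshold, and that of Pla2g12a stood at 0.20, in the other direction. Mir686 is a microRNA gene that lies within Psmb5, and its annotated probe set was not shown to measure the microRNA. Of 6124 genes, 41 were higher and 100 lower in 129, so that 70.9% of the called genes were lower (95% Wilson interval 63.0% to 77.8%).

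Genes of the complement component C1q, which brain microglia make, were lower in 129 in 20 of 20 neural tissues: C1qc by -0.71 ± 0.06, C1qb by -0.69 ± 0.04 and C1qa by -0.67 ± 0.05 (limma adjusted p = 2.88e-17, 5.41e-22 and 1.48e-17). The other probe set of C1qb did not pass and stood at 0.22, in the other direction, and in telencephalic tissues alone C1qa and C1qc fell short of 1.5-fold, at -0.56 and -0.52. Of 9 microglial genes these 3 were called, 3 adjusted over the list alone (camera adjusted p = 1.75e-10). Of the genes known to vary between inbred strains, Gabra2 was higher in 129 by 1.33 ± 0.10, Glo1 by 1.07 ± 0.03, Alad by 0.90 ± 0.04 and Nnt by 0.65 ± 0.07, which made 4 of 4, 4 adjusted over the list alone (6.93e-14). Nnt fell to 0.39 in telencephalic tissues alone. In body tissue 2 of 3 were higher, 2 adjusted over the list alone (2.20e-05), Glo1 by 1.38 ± 0.12 and Alad by 1.11 ± 0.19. Of 3 red blood cell genes Hbb-b2 was called, 1 adjusted over the list alone (0.000161). None of 10 immediate early genes passed, 0 adjusted over the list alone (0.775), and none of 2 sex-linked genes, 0 adjusted over the list alone (0.828), while 2080 genes of the whole limma comparison had an unadjusted p under 0.05.

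Separate arrays of body tissue gave the same direction for most of these genes. Gdpd3 was higher in 129 by 2.99 ± 0.32 (limma adjusted p = 7.40e-09, 10 against 10 arrays), Pam by 2.75 ± 0.51, Cap1 by 2.67 ± 0.30, Gbp2b by 2.27 ± 0.47, Ocel1 by 1.64 ± 0.16, Erdr1 by 1.55 ± 0.36 and Ssr1 by 1.49 ± 0.20. Snhg6 was lower by -3.44 ± 0.25, Arcn1 by -2.90 ± 0.14, Gas5 by -2.90 ± 0.36, the probe set annotated to Mir686 by -2.77 ± 0.19, AI506816 by -2.46 ± 0.27, Pla2g12a by -2.07 ± 0.17, Fgfr1op2 by -1.97 ± 0.15 and Slc1a5 by -1.92 ± 0.36. In the unfiltered fit of all probe sets, the other probe sets of Erdr1, Ssr1, Snhg6, AI506816 and Pla2g12a did not pass. Of 137 genes called in neural tissue and tested in body tissue, 125 had the same sign, or 91.2% (95% Wilson interval 85.3% to 94.9%), against 55.3% of all 5682 genes tested in both. Calls with the same sign in both numbered 16 higher and 54 lower, where independent lists would share 0.432 and 2.24, and 0 were opposite. Both comparisons used the same probe set for a gene. A probe sequence that matches 1 strain better would give the same sign in both, so shared calls alone do not show a difference in expression. Of 6680 genes in body tissue, 67 were higher and 154 lower in 129. Under quantile normalization the split became 98 and 126.

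**Figure D3:**
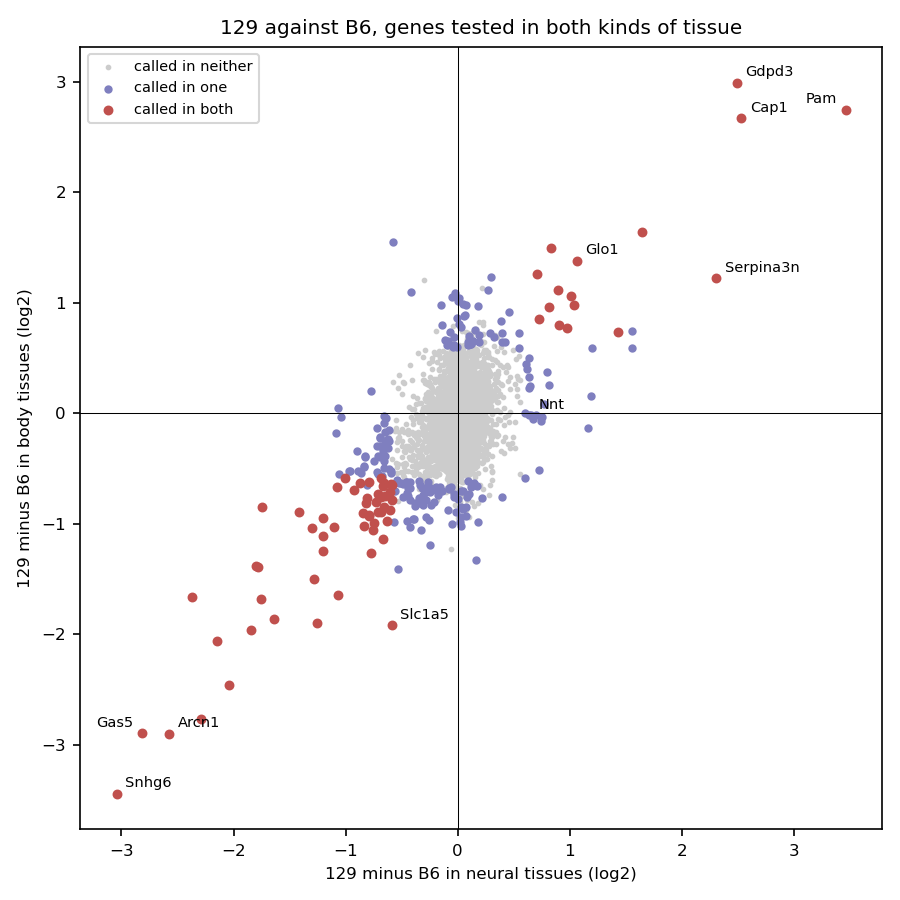
Difference 129 minus B6 (log2) in neural tissues (horizontal axis) and in body tissues (vertical axis), a point per gene tested in both. The 70 genes called in both kinds of tissue had the same sign in both.

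All 5 strains were compared in the body tissues. H2-Ea, a class II antigen presentation gene, differed between B6 and DBA by 3.93 (limma F test, adjusted p = 0.000121, 50 arrays), with C3H at 1.83 above B6, AJ at 0.60 and 129 at 0.09. Snhg6 set B6 apart from the rest: AJ, C3H and DBA lay -3.46, -3.15 and -3.53 from B6. The probe set annotated to Mir686 and that of Cap1 behaved likewise, with AJ at -2.49 and 2.78. Gdpd3, Arcn1 and Pla2g12a set 129 apart, since Arcn1 in AJ, C3H and DBA lay 0.14, 0.02 and 0.19 from B6. Pdxdc1 was low in C3H and DBA, at -3.47 and -3.40, and less so in 129 and AJ, at -0.54 and -0.69. In neural tissue its other probe set did not share the difference of 129 from B6, at -0.02 against -0.60. Strain levels here come from 1 probe set per gene, and a probe sequence that matches 1 strain better would also shift them. The test called 529 of 6680 genes. Against B6, 375 genes were lower and 100 higher in AJ, 71 and 25 in C3H, and 75 and 43 in DBA. These contrasts share the same 10 B6 arrays and were not rerun under another scaling.

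The last question was whether the strain difference depends on the tissue. Erdr1 differed by -0.58 ± 0.18 in neural tissue, short of 1.5-fold and not called there, and was higher in 129 in body tissue (1.55 ± 0.36), a difference of 2.13 ± 0.44 (limma adjusted p = 0.000386, 100 arrays). Med1 likewise moved from -0.42 to 1.10. The extracellular matrix gene Fmod went from 0.17 to -1.33, a call that ended without muscle 129 replicate 1 (-1.04). Of 7161 genes, 1205 had such an interaction with arrays as the units, where tissues regrouped at random gave up to 714. Among the 19 neural tissues the interaction reached 1268 of 6119 genes over 77 arrays. Its strongest genes included the splicing kinases Clk4 and Clk1, Hnrnpu and the imprinted noncoding gene Meg3, all named after their values were seen. In choroid plexus they were higher in 129 by 3.24, 3.28, 4.09 and 3.50, from 2 arrays per strain, and in amygdala they differed by -0.46, -0.02, 0.07 and 0.16. Leaving out any array of choroid plexus removes that tissue from the test, and 395 genes then had an interaction, without Clk4 (adjusted p = 0.0689), Clk1, Hnrnpu and Meg3.

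**Figure D4:**
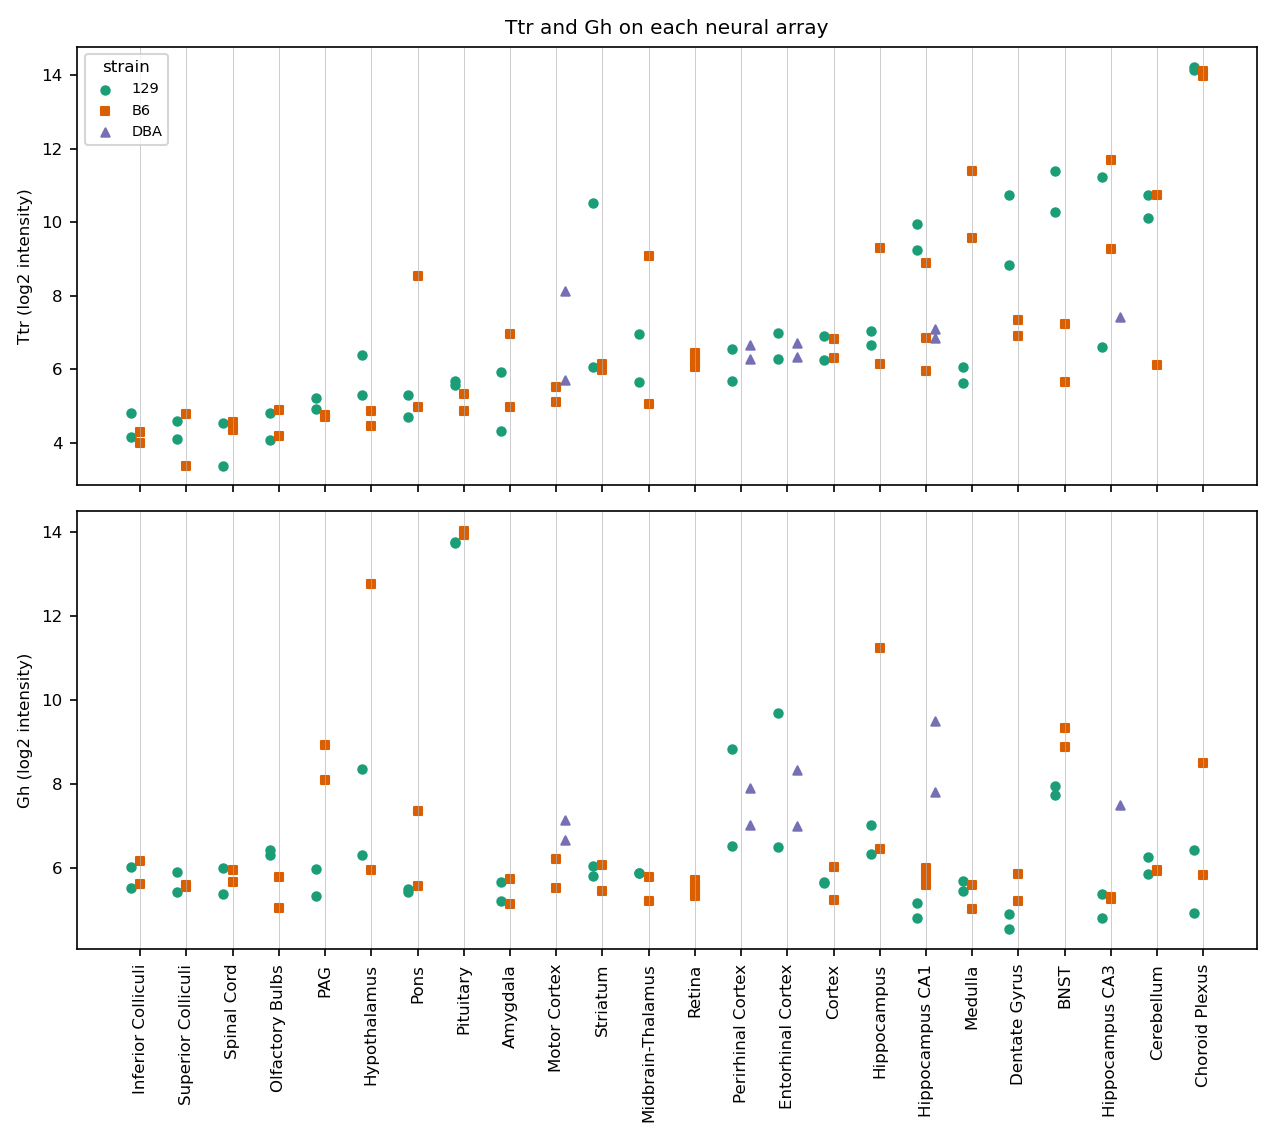
Ttr and Gh intensity (log2, vertical axes) on every neural array, by tissue and strain. Both genes reached high values on single arrays of brain tissue, such as Ttr at 10.52 in striatum 129 replicate 1 and Gh at 12.77 in hypothalamus B6 replicate 1.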

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

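The tests of the identical arrays and of pituitary RNA were chosen only after the result was seen, and for Ttr, Gh and Xist the restriction to tissues with an array above 5.73 was added after the first flags. Arrays far from the others of their tissue were sought in 76 pairs of tissue and measure. Of these, 14 held such an array, against 3.8 at the nominal rate of 1 in 20. That rate is not a valid chance level here. For Ttr, Gh and Xist the restriction selected tissues with a high array, and mean correlations within a tissue are not independent.

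For the mean correlation with the other arrays of the tissue, the low arrays were entorhinal cortex DBA replicate 1 (0.962), CA1 DBA replicate 1 (0.919), brown fat DBA (0.941), liver B6 (0.946) and white fat AJ (0.954). Ttr stood at 6.10 in cerebellum B6 replicate 2, below the other arrays at 10.12 to 10.76, at 8.54 in pons B6 replicate 2, above 4.69 to 5.29, and at 10.52 in striatum 129 replicate 1, above 5.99 to 6.14. Gh stood at 7.50 in CA3 DBA replicate 1, above 4.80 to 5.39, at 5.21 in midbrain with thalamus B6 replicate 2, below 5.78 to 5.89, and at 7.36 in pons B6 replicate 1, above 5.44 to 5.58. Xist, which is expressed from the inactive X chromosome of females, stood at 7.46 in spinal cord 129 replicate 2 and at 3.38 on the other arrays. The mean of the skeletal muscle genes stood at 5.17 in testes 129, above 4.69 to 4.79, and at 8.19 in thymus C3H, above 4.83 to 5.12.

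Of 26 named strain genes, 12 had a difference between 129 and B6 that itself differed between body and neural tissue in the limma interaction test. The difference in body minus that in neural tissue was 0.39 for C1qb (adjusted p = 0.0111), -0.81 for Hbb-b2 (adjusted p = 0.0163), -1.39 for Gabra2, 0.31 for Glo1 (adjusted p = 0.00643) and -0.66 for Nnt (adjusted p = 0.00153). Gabra2 was below the filter in every body tissue, at a mean of at most 3.74, so its value tests no difference there. For the others it was -1.09 for Serpina3n, -0.97 for Fv1, -0.70 for Gnb1, -0.48 for the probe set annotated to Mir686, 2.13 for Erdr1, 0.66 for Ssr1 and -1.33 for Slc1a5.

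The column labelled DBA perirhinal cortex replicate 2 and the column labelled 129 hippocampus replicate 1 held the same values. Of 101 genes that differ between 129 and DBA in body tissue, 18.8% were nearer to 129 (95% exact interval 11.7% to 27.8%) and 81.2% nearer to DBA. Of 306 genes that differ between hippocampus and perirhinal cortex, 20.6% were nearer to hippocampus (16.2% to 25.6%) and 79.4% nearer to perirhinal cortex. These values argue against a 129 hippocampus sample and go with a DBA perirhinal cortex sample. The intervals treat genes of the same array as independent, and the highest single correlation was with entorhinal cortex 129 replicate 1, at 0.978. The origin of the values is therefore not settled. Both columns stayed out of every comparison, and no biological explanation was tested.

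High Ttr or Gh in single brain arrays could come from adjoining tissue. Over 86 brain and cord arrays, Ttr centred per tissue went with the mean of 6 other choroid plexus genes at Pearson r = 0.834 (permutation p = 1e-05, the smallest they can give), Spearman rho = 0.739, and r = 0.805 without the 2 arrays farthest in Ttr. The excess of those genes was only a median of 0.247 of that predicted from Ttr (0.110 to 0.326), and Ttr was the brightest probe set on every choroid plexus array, at a mean of 17873, so that its scale may be compressed there and the test cannot tell. Hippocampus B6 replicate 2 had Gh at 11.25 and Prl at 8.05, against Gh at 6.35 and 6.47 on the other hippocampus arrays used, and its excess was not tested. In hypothalamus B6 replicate 1, Gh stood at 12.77 against at most 8.35, and 5 of 10 other pituitary genes exceeded every other array of the tissue. Their excess was a median of 0.0136 of that predicted from Gh, or 0.0598 of that predicted from Prl, but Gh was also near the maximum of the pituitary arrays (14924 of 14964), so pituitary RNA stays open, and no biological explanation was tested.

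More genes were lower than higher in 129. Scaling and RNA quality do not account for it in neural tissue, since 72.0% of called genes were lower under quantile normalization and 70.9% with the Gapdh ratio as covariate. Among genes lower in 129 with a further probe set that passed the filter, the difference at that probe set was a median of 0.0663 of the called one (13 genes, with 8 ratios under 0.25 and 3 of at least 0.75), and 0.856 for 7 genes higher in 129 (9 probe sets, with 3 ratios under 0.25 and 5 of at least 0.75). This is consistent with probe sequences that match B6 better than 129 for part of the genes, with widely spread ratios and few genes. For 5 of the 13 the further probe set was called in the same direction, and no biological explanation of the direction was tested.

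Arrays or tissues were regrouped at random in 100 splits that include the real one. In most comparisons no other split reached the real count, with 1 split of 100 at that count in each. The real count was 2041 genes against at most 225 for neural and body tissue, and 396 against 316 for telencephalon and hindbrain. It was 3013 against 633 for the neural tissues, 4955 against 1244 for the body tissues, and 1650 against 993 for the fat depots. For strains it was 141 against 25 in neural tissue, 221 against 1 in body tissue, 529 against 1 for 5 strains, and 1205 against 714 for strain and kind of tissue. So few splits bound chance at about 1 in 100 and cannot exclude it. The highest random splits reached 316, 993 and 714 genes. A random split can keep part of the real grouping, so these maxima do not show how many genes arise without it. For CA1 and dentate gyrus the real count of 39 was also reached by 1 split only, with 36 as the next. For CA1 and CA3, and for CA3 and dentate gyrus, the real count was 0, which every split reaches (100 of 100, with at most 48 and 21), so the splits test nothing there.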

How the results depend on the processing

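The floor at the 10th percentile (3.28), quantile normalization of the intensities, the fits with both identical arrays kept, the counts over brain and cord tissues in the same fit and the fit without the pair of B6 arrays with pituitary hormone signal (hypothalamus replicate 1 and hippocampus replicate 2) were chosen after seeing the data. So was the count for the fat depots without genes also higher in skeletal muscle. The planned floor at the 5th percentile was not run, since that percentile is -1.06 and has no log2. Of 5534 values for 333 named gene results, 5426 kept direction and call, 108 lost the call and 0 reversed. For 34 of these results some array or tissue left out ended the call. Of 255 values of counts and similarity, 239 stayed within 1.5 times.

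CA1 against dentate gyrus gave 7 genes with no filter, 20 with the Gapdh ratio as covariate and 63 with all neural arrays in the fit, which gave 7 for CA1 against CA3 and 9 for CA3 against dentate gyrus. The last gave 1 with no trend in the prior and 2 with the animal pool as replicate block. The cause was not tested. A stricter filter tests fewer genes and left 1963 higher among neural tissues and 80 between strains in neural tissue. Brain and cord tissues alone gave 1196 higher and 1030 lower, or 1307 and 1063 in the same fit. A 2-fold threshold, stricter by construction, left 44 genes between strains in neural tissue, 59 in body tissue and 152 for 5 strains. The body strain split went from 30.3% to 43.8% higher under quantile normalization, a shift whose cause was not tested.

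With single arrays left out, counts ran from 15 to 60 for CA1 against dentate gyrus, 0 to 11 for CA1 against CA3, 0 to 1 for CA3 against dentate gyrus, and 395 to 1645 for strain by neural tissue. Others stayed within 1.5 times: 138 to 145 genes for strains in neural tissue, 186 to 255 in body tissue, 419 to 605 for 5 strains, 934 to 1385 for strain and kind of tissue, and 1579 to 1776 for fat depots. With tissues left out, similarity ran from 0.406 to 0.534. The preset list tests called 45 of 56 pairs, 43 to 46 under alternatives and 32 with an estimated correlation. Lists were not rerun with arrays left out.

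Residuals of arrays that shared a pool number had a median correlation of 0.0789 over 31 neural pairs and 0.0382 over 22 body pairs. The block correlation was 0.171 for regions, 0.376 for subfields, 0.0374 for body tissues and 0.145 for neural strains, and the block moved no other count by over 1.5 times. Signal near background limits dim genes, since up to 25.8% of an array's probe sets lay at the floor.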

Other observations

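Mean levels of cell type lists across tissues belong in no comparison above. Myelin genes were highest in spinal cord (mean log2 9.77), pons (9.33) and medulla (9.23), and lowest among neural tissues in retina (4.56), whose ganglion cell axons are unmyelinated within the eye. Astrocyte genes were also highest in spinal cord (10.72) and medulla (10.38). Microglial genes were highest among neural tissues in striatum (7.38) and lowest in retina (5.20) and cerebellum (5.98), and spleen stood above all at 8.94. Immediate early genes were highest in olfactory bulbs (8.09) and pituitary (7.96). Genes of dividing cells stood at 8.65 in thymus, 7.99 in spleen and 7.52 in testes, and at 4.54 in periaqueductal grey. These are means without a test.

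Skeletal muscle genes varied among the brown fat arrays. Their mean was 9.30 in C3H, 8.42 in B6, 8.00 in AJ, 7.97 in 129 and 4.82 in DBA, against 4.23 to 4.96 in white fat and 11.44 to 11.79 in muscle. The same mean was 8.20 in adrenal 129, against 4.25 to 5.49 on the other adrenal arrays. Of the 814 genes lower in brown fat, 104 were also higher in skeletal muscle than in the other body tissues, which leaves 710.

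The test of neighbouring genes was chosen only after the strain result was seen. If strains differ by inherited segments, genes called between 129 and B6 could lie next to each other. In neural tissue 13 of 140 called genes with a position had a called neighbour, against a median of 6 and a 95th percentile of 12 in random draws (permutation p = 0.0391). With C1qa, C1qb and C1qc, which are adjacent genes, not counted as called, 10 remained (permutation p = 0.173). In body tissue it was 23 of 219, against 14 and 22 (permutation p = 0.0485). The hypothesis stays undecided: the neural result rests on the C1q genes, and the body result, in which they were not called, lay just past the bound.

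In choroid plexus, further genes with a strong interaction, chosen after their values were seen, were higher in 129 than in B6, from 2 arrays per strain: Ccl9 by 4.94, Mdm4 by 3.19, Paxbp1 by 2.93, Ccnl2 by 2.46 and Eif5 by 1.91. With any array of choroid plexus left out, which removes that tissue from the test, the interaction was lost for Mdm4, Paxbp1, Ccnl2 and Eif5 (limma adjusted p = 0.545, 0.676, 0.590 and 0.818), and Ccl9 was not tested. Ctse differed by 0.83 there and by -1.84 in the bed nucleus of the stria terminalis.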
